A study of Mus musculus with 10 samples.

How the data were processed

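Gene expression was measured with Affymetrix arrays in total RNA from the brain hemisphere on the operated side of male mice, 24 h after middle cerebral artery occlusion (MCAO, a model of stroke) or sham surgery. The 10 arrays fall into 4 groups: wild-type (WT) sham with 2 arrays, WT MCAO with 3, Hsp72Tg sham with 2 and Hsp72Tg MCAO with 3. Hsp72Tg mice carry a transgene for overexpression of Hsp72, the inducible heat shock protein made from Hspa1a and Hspa1b. Samples are named here by group and replicate number.

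The deposited values are log2 RMA expression values, 1 per probe set and array, made with RMA per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarizes the probes of a probe set. The version of that software and its settings are not given in the sources used here. The values ran from 3.49 to 14.7 with 0 missing, and array medians lay between 6.67 and 6.73, which fits log2 values normalized between arrays. Scanner files were not used here, so no background flag per probe set was applied and the precision is set by the number of arrays.

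The table held 45101 probe sets, of which 64 were control probe sets and were left out of the tests. Of the rest, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 were not listed there and stayed unnamed. Symbols were updated through Entrez identifiers in the RefSeq gene table of the assembly GRCm38.p6. There 34741 probe sets matched and 0 symbols changed. Each gene was represented by its probe set with the highest mean over the 10 arrays, which mattered for 9010 genes with more than 1 probe set and left 18193 genes.

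Tests used limma 3.58.1 in R 4.3.3 on the log2 values, with lmFit, contrasts.fit and eBayes and a mean per group over all 10 arrays. This fit had 6 residual degrees of freedom and a prior of 3.72. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The contrasts were MCAO minus sham in WT, in Hsp72Tg and averaged over both genotypes, the difference of the MCAO changes between genotypes, and Hsp72Tg minus WT after MCAO, after sham surgery and averaged over both. Errors are standard errors (SE) of the contrast or, where stated, the SD within a group. Intervals are 95% confidence intervals of the contrast.

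The 32 gene lists held 448 genes, of which 411 were measured, and covered stress responses, reactive astrocytes, brain and blood cell types, inflammation, vessels, matrix and brain regions. They were tested with limma's camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with limma's fry, which tests each list on its own. Exact permutation tests of list means, two-sided, exchanged MCAO and sham labels within genotype or genotype labels within surgery. Counts within a list are given over all genes and adjusted over the list alone.

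The comparisons, the lists, the alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. The rule took Hspa1a and Hspa1b always. In each genotype it took up to 8 genes per direction with the largest changes after MCAO among those that passed and whose MCAO arrays all lay on 1 side of the sham arrays. It took up to 3 members with the largest absolute change for each list, and for each comparison of genotypes the 3 genes per direction with the smallest p where none passed. Clone and predicted gene names were passed over.

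The analysis was tested on simulated data with 200 of 18193 genes changed, in 20 simulations per comparison. At a log2 change of 1 it recovered 80.8% of changed genes for MCAO in WT, 82.7% for MCAO in Hsp72Tg, 92.8% for MCAO over both genotypes, 57.8% for the difference of the MCAO changes, 86.6% for genotype after MCAO, 76.2% for genotype after sham surgery and 93.7% for genotype over both surgeries. These simulations drew genes independently, with the same spread in every array, and shifted randomly chosen genes. The real arrays differed in spread, and 263 genes changed over 2-fold in WT while 10 genes passed. The shares are thus not the power reached in these data. For MCAO in WT, camera recovered 97.5% of lists shifted by a log2 value of 0.5. Genes were drawn independently there too, so this share does not test the preset correlation between genes. In the real data camera called 22 lists for that comparison at the preset correlation and 0 with an estimated correlation. The share is thus not the power of the list tests in these data.

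Alternatives were the replicate number as a block, only the arrays of the groups compared, eBayes with trend and robust options, limma's arrayWeights, quantile normalization of the deposited values, centring on array medians, the mean over a gene's probe sets, every probe set on its own, a filter on dim probe sets, an adjusted p under 0.01, a minimum 2-fold change and leaving out each array. Chosen after seeing the data were fits without a pair of doubted arrays, the list tests for MCAO over both genotypes and the exact tests of lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.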

Results

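The series asks how Hsp72 overexpression relates to the response of the mouse brain to stroke, with attention to astrocytes. RNA of 10 hemisphere samples was measured: WT sham (n = 2), WT MCAO (n = 3), Hsp72Tg sham (n = 2) and Hsp72Tg MCAO (n = 3), each 24 h after surgery. The values are log2 RMA expression values for 18193 genes. Every pair of arrays correlated across genes at r between 0.977 and 0.997, where genes are not independent replicates. The first principal component held 50.3% of the variance. On it the sham arrays lay between -23.7 and -20.7 and 5 of the MCAO arrays between 11.7 and 32.3. The array Hsp72Tg MCAO 1 lay at -12.9, nearer to the sham arrays.

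Hspa1b and Hspa1a, which encode Hsp72, were read first because the genotype labels concern them. Hspa1b had a mean log2 value of 9.43 ± 0.07 (SD, n = 2) in WT sham, 12.47 ± 0.54 (n = 3) in WT MCAO, 9.14 ± 0.02 (n = 2) in Hsp72Tg sham and 13.04 ± 0.95 (n = 3) in Hsp72Tg MCAO. Hspa1a had means of 8.50 ± 0.06, 11.15 ± 0.48, 8.41 ± 0.18 and 11.99 ± 1.31 in the same groups. After sham surgery Hspa1b was thus not higher in Hsp72Tg than in WT, with a difference of -0.29 (SE 0.51, adjusted p = 1), and Hspa1a differed by -0.09 (SE 0.64). These SEs pool the spread of all 4 groups, which was wider after MCAO than in the sham arrays. Hspa1b read 9.120 and 9.155 in Hsp72Tg sham, below 9.378 and 9.480 in WT sham. All 3 probe sets of Hspa1b and the probe set of Hspa1a had a lower mean in Hsp72Tg sham than in WT sham. The difference of Hspa1a turned to 0.04 without Hsp72Tg sham 1. The labels do not give the species or construct of the transgene, so a probe set that does not match its sequence checks nothing, and the genotype labels are unchecked here. After MCAO, Hspa1b was 0.56 (SE 0.41, interval -0.36 to 1.49) and Hspa1a 0.84 (SE 0.52, interval -0.33 to 2.01) higher in Hsp72Tg than in WT, and neither passed. Without Hsp72Tg MCAO 2 these differences were 0.10 and 0.22, without Hsp72Tg MCAO 1 they were 1.05 and 1.52, and that of Hspa1b was 0.25 without WT MCAO 1. Over both surgeries Hspa1b differed by 0.14 (SE 0.33) and Hspa1a by 0.37 (SE 0.41). The Hspa1b difference over both surgeries turned to -0.02 without WT MCAO 1 and to -0.09 without Hsp72Tg MCAO 2, and was 0.38 without Hsp72Tg MCAO 1 and 0.23 without WT MCAO 2. That of Hspa1a was 0.06 without Hsp72Tg MCAO 2, 0.24 without WT MCAO 1 and 0.72 without Hsp72Tg MCAO 1.

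**Figure D1:**
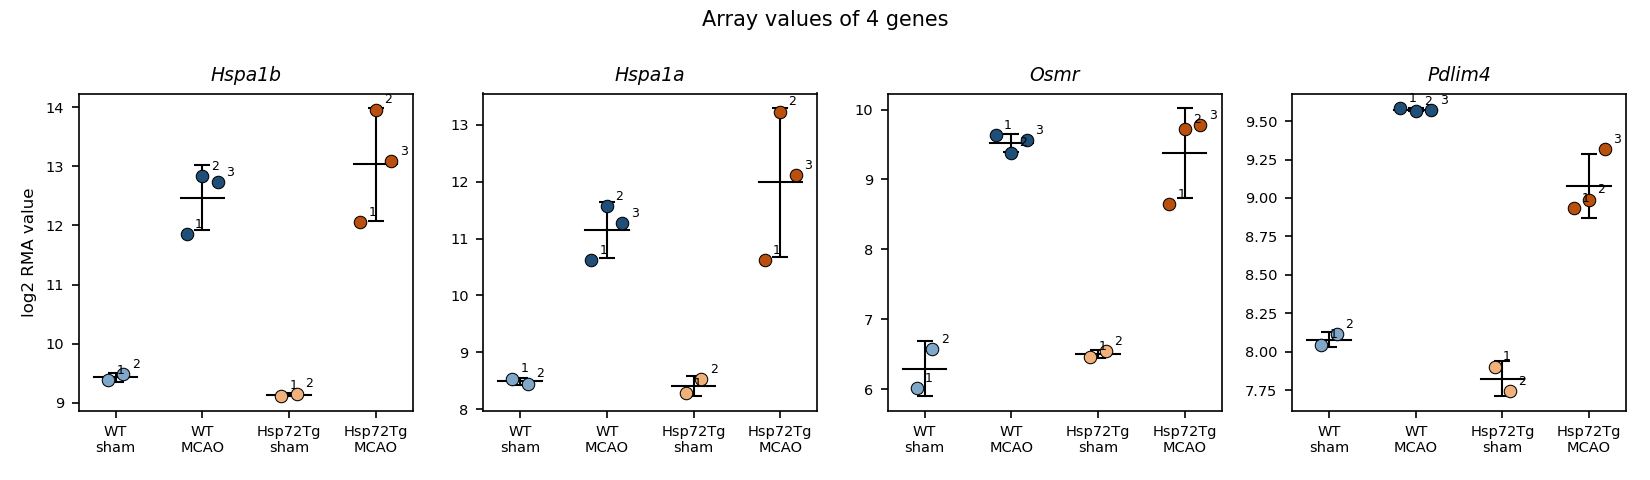
Log2 RMA values of Hspa1b, Hspa1a, Osmr and Pdlim4 in each of the 10 arrays, by group. Points are arrays with their replicate number, horizontal lines group means and bars 1 SD, and the MCAO arrays of Hspa1b lie between 11.85 and 13.96 against 9.12 to 9.48 in the sham arrays.

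MCAO was first compared with sham over both genotypes, with 6 arrays against 4. Both Hsp72 genes rose, Hspa1b by 3.47 on the log2 scale (SE 0.33, adjusted p = 0.00343) and Hspa1a by 3.12 (SE 0.41, adjusted p = 0.014). Osmr, the receptor subunit for oncostatin M, rose by 3.06 (SE 0.22, adjusted p = 0.000746), and Hspb1, a small heat shock protein, by 2.85 (SE 0.26, adjusted p = 0.00343). The 3 probe sets of Osmr changed by -0.05 to 3.06, so the size of its rise depends on the probe set. Cd44, a hyaluronan receptor, rose by 3.35 (SE 0.32), Lcn2, the iron-binding lipocalin, by 4.38 (SE 0.84) and Lgals3, the lectin galectin-3, by 3.48 (SE 0.46). The 4 probe sets of Cd44 changed by -0.04 to 3.35, so the size of its rise depends on the probe set too. Below, the same holds among others for Emp1 (2 probe sets, 0.36 to 3.42) and Lif (2, 0.28 to 2.28). It also holds for Mmp14 (3 probe sets, 0.04 to 0.83). Tph2, the enzyme of serotonin synthesis in neurons, fell by 1.62 (SE 0.17). In limma 266 genes passed, 192 higher and 74 lower, and 3478 had an unadjusted p under 0.05 against 910 by chance. The count was 17 without WT sham 1, 23 without WT sham 2, 11 without Hsp72Tg sham 1, 93 without Hsp72Tg sham 2, 27 without WT MCAO 1, 40 without WT MCAO 2, 15 without WT MCAO 3 and 2251 without Hsp72Tg MCAO 1, with all 266 genes among the 2251 and all 266 of the same sign in each of these fits. The 266 genes were chosen in these same arrays, so their kept sign is no independent support. Lcn2, Lgals3 and Tph2 belong to a list or a comparison within a genotype that the naming rule covers.

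The RNA came from hemisphere tissue and not from separated cells, so no gene list here assigns a change to a cell type. Of the lists fixed for reactive astrocytes, the pan-reactive astrocyte genes moved most broadly over both genotypes. Here 12 of 13 measured members rose over all genes, and 12 rose adjusted over the list alone, with a list mean of 2.27 (interval 1.51 to 3.03). Gfap, the filament protein by which astrocytes are usually recognised, rose by 1.60 (SE 0.19, adjusted p = 0.0113) and Vim, another filament protein, by 1.98 (SE 0.24); both were named after their values were seen. Camera called this list higher (adjusted p = 2.41e-23), and the call was lost at adjusted p = 0.157 with an estimated correlation. Of the 12 A2 reactive astrocyte genes, 7 rose over all genes and 10 adjusted over the list alone, with a mean of 1.66, among them Emp1 (3.42, SE 0.60), the lipopolysaccharide co-receptor Cd14 (3.36, SE 0.56) and the transglutaminase Tgm1 (2.70, SE 0.42). Tgm1 read 4.93 to 5.17 in the sham arrays, each below the lower quartile of its array, so the size of its rise is uncertain. Of the 9 measured A1 reactive astrocyte genes, 0 passed over all genes in limma and 6 rose adjusted over the list alone, with a mean of 0.76 and 8 of 9 higher in value. Camera called both lists higher, with adjusted p = 0.157 for each with an estimated correlation, and fry gave adjusted p = 0.0318 for A2 and 0.0505 for A1. The 18 astrocyte markers of normal brain had a mean of 0.04 and a median of -0.04, and 0 passed in limma over all genes against 1 higher and 1 lower adjusted over the list alone. Camera did not call them (adjusted p = 0.646, and 0.866 with an estimated correlation).

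**Figure D2:**
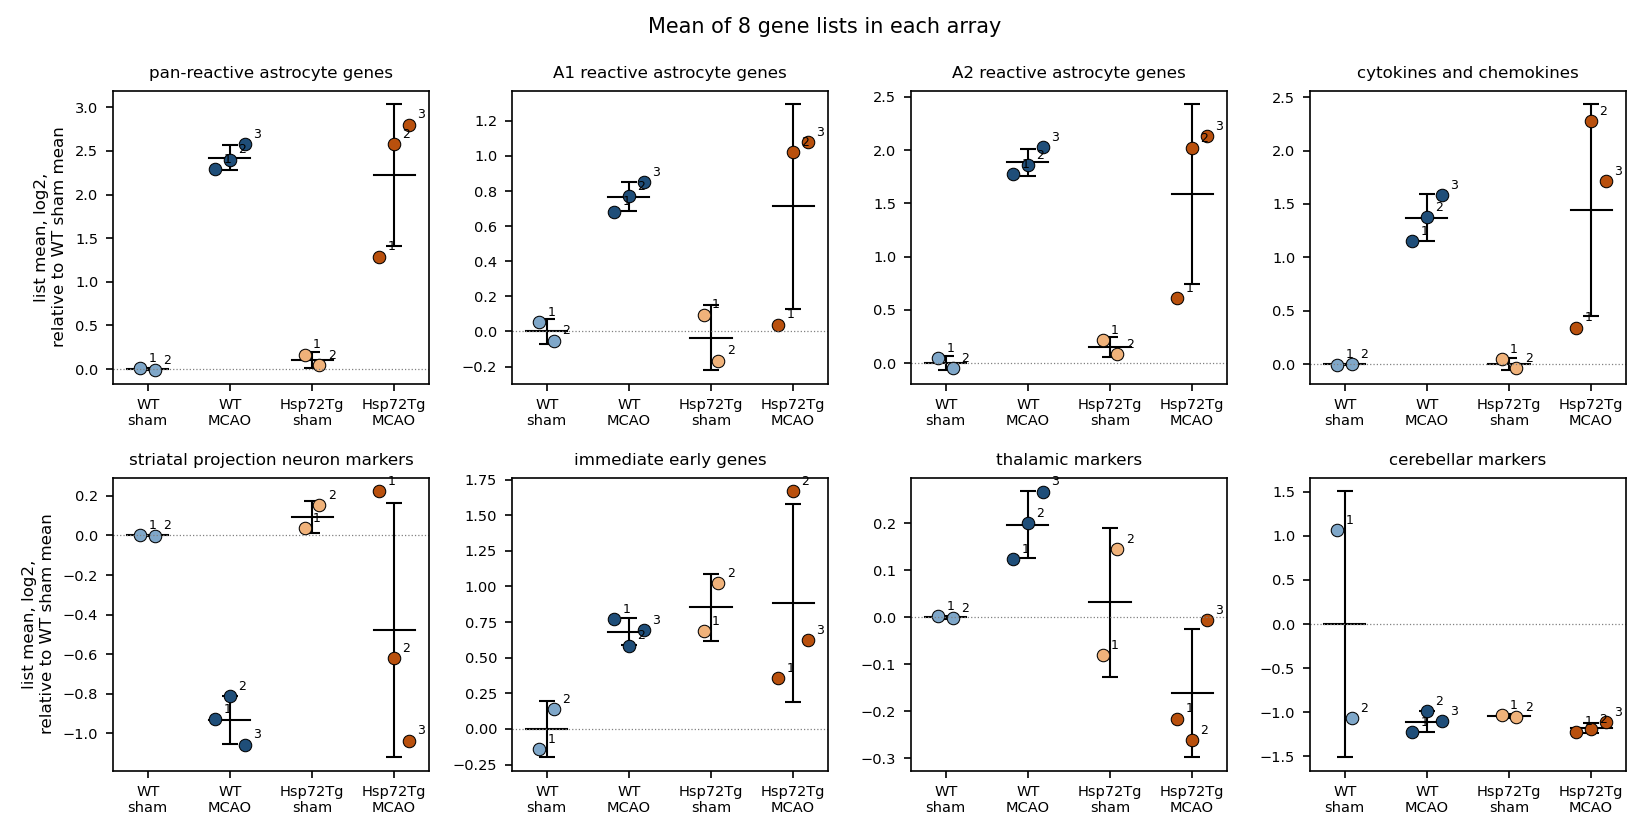
Mean log2 value of 8 gene lists in each array, relative to the WT sham mean. Points are arrays with their replicate number, horizontal lines group means and bars 1 SD; Hsp72Tg MCAO 1 lies below the other MCAO arrays for the pan-reactive, A1 and A2 astrocyte lists and for cytokines, and WT sham 1 lies above the other arrays for cerebellar markers.

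Inflammatory lists were also higher after MCAO over both genotypes. Among 21 cytokines and chemokines, 3 rose over all genes and 16 adjusted over the list alone, with a mean of 1.41. The chemokines Ccl12 and Cxcl10 rose by 3.17 (SE 0.33) and 2.23 (SE 0.37) and the cytokine Lif by 2.28 (SE 0.36), while Il6 at 3.21 (SE 0.76) and Cxcl2 at 2.96 (SE 0.98) did not pass over all genes. Sham values of Il6 (4.39 to 4.77) and Cxcl2 (4.44 to 4.88) lay below the lower quartile of every array (at least 5.14). The sizes of these 2 changes are thus uncertain. Of 17 activated microglia and macrophage genes, 4 rose over all genes and 13 adjusted over the list alone, led by Lgals3, the lysosomal protein Cd68 (1.35, SE 0.18) and the pattern receptor Tlr2 (1.38, SE 0.20), with the cathepsin Ctsz (0.79, SE 0.13) as the other. Of 19 interferon-stimulated genes 1 rose over all genes and 12 adjusted over the list alone, and of 10 complement genes 1 and 6 did. Here Xaf1, an interferon-induced regulator of apoptosis, rose by 0.49 (SE 0.09) and the complement receptor C3ar1 by 1.33 (SE 0.18). Cxcl10, Lif, Ctsz and Xaf1 were named after their values were seen, to name all members that passed. Camera called these 4 lists higher, with adjusted p = 0.157 for each with an estimated correlation. The lists of neutrophil markers (mean 0.64, 11 genes) and monocyte markers (mean 0.37, 9 genes) were called higher by camera although 0 genes passed in limma over all genes or adjusted over the list alone. For both lists adjusted p = 0.314 with an estimated correlation, and the monocyte call was lost without Hsp72Tg sham 2 (adjusted p = 0.0714). Lymphocyte markers (mean -0.06, 9 genes, 1 lower adjusted over the list alone) and microglia markers of normal brain (mean -0.40, 11 genes, 1 lower adjusted over the list alone) were not called with all arrays. The microglia mean was -0.57 without WT sham 1, and camera called it lower without Hsp72Tg MCAO 1 (mean -0.54, adjusted p = 0.00936). Relative to the WT sham mean, that list read -0.34 in WT sham 1, 0.34 in WT sham 2 and -0.87 in Hsp72Tg MCAO 2, the lowest array. Its fall is thus smaller without WT sham 2 or Hsp72Tg MCAO 2. Among the microglia markers P2ry12, a purinergic receptor of resting microglia, had a change of -1.67 (SE 0.37, adjusted p = 0.0586).

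Stress, vessel and matrix genes formed a further set of lists over both genotypes. Of 13 antioxidant and metal response genes 6 rose over all genes and 9 adjusted over the list alone, among them heme oxygenase Hmox1 (2.43, SE 0.39) and the metallothioneins Mt2 (1.31, SE 0.27) and Mt1 (0.88, SE 0.17). Of 16 extracellular matrix and scar genes 5 and 11 rose, with tenascin Tnc at 2.10 (SE 0.40), Tgfbi at 2.13 (SE 0.43), the collagen Col4a1 at 1.68 (SE 0.28), the protease Mmp14 at 0.83 (SE 0.13) and the integrin Itga5 at 0.80 (SE 0.12). Of 11 endothelial activation genes 2 and 10 rose, with the protease Adamts1 at 2.74 (SE 0.39) and von Willebrand factor Vwf at 1.22 (SE 0.21), and of 14 endothelial and blood-brain barrier markers 2 rose over all genes, with 8 higher and 2 lower adjusted over the list alone, where the junction protein Pecam1 rose by 1.0 (SE 0.18) and the tight junction protein Cldn5 by 0.65 (SE 0.12). Col4a1, Mmp14, Itga5, Vwf and Cldn5 were named after their values were seen. The 18 p53 targets and apoptosis regulators had 1 member that rose, Casp8 (0.72, SE 0.13), and 8 higher and 1 lower adjusted over the list alone. Beyond Hspa1a and Hspa1b, 18 heat shock proteins and co-chaperones had 1 member that rose over all genes, Hspb1, and 7 higher and 1 lower adjusted over the list alone. The 18 endoplasmic reticulum stress genes had 0 in limma over all genes and 6 adjusted over the list alone, and the transcription factor Atf3 stood at 2.23 (SE 0.50, adjusted p = 0.0638). Camera called these 7 lists higher, with adjusted p from 0.157 to 0.179 with an estimated correlation. Immediate early genes were called higher (mean 0.36, 23 genes, Fosl1 rose by 1.65, SE 0.34; 8 higher and 1 lower adjusted over the list alone) with adjusted p = 0.548 with an estimated correlation. That call was lost without Hsp72Tg MCAO 2 (mean 0.16, adjusted p = 0.113) and without Hsp72Tg sham 1 (adjusted p = 0.074). Hypoxia response genes were not called with all arrays (adjusted p = 0.158; higher without WT sham 2, 0.0475), although 2 of 15 rose over all genes and 2 adjusted over the list alone, the hexokinase Hk2 by 0.98 (SE 0.11) and the vasodilator peptide Adm by 0.96 (SE 0.20).

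Neuronal lists were lower after MCAO over both genotypes. All 10 striatal projection neuron markers had lower values, with a mean of -0.75 (interval -1.35 to -0.15). In limma 0 passed over all genes and 9 were lower adjusted over the list alone, among them the phosphodiesterase Pde10a (-1.0, SE 0.26) and the sodium channel subunit Scn4b (-1.0, SE 0.26). Camera called the list lower, with adjusted p = 0.227 with an estimated correlation. General neuronal markers (mean -0.16, 15 genes, 0 over all genes in limma or adjusted over the list alone) were called lower by camera, with adjusted p = 0.55 with an estimated correlation, and the call was lost without Hsp72Tg MCAO 3 (adjusted p = 0.089) and Hsp72Tg sham 2 (adjusted p = 0.172). Cerebellar markers (mean -0.62, 8 genes, 0 over all genes in limma or adjusted over the list alone) were called lower, with adjusted p = 0.493 with an estimated correlation. That mean was -1.16 without WT sham 2, and the call was lost without WT sham 1 (mean -0.0858, adjusted p = 0.653), Hsp72Tg sham 2 (0.177), WT MCAO 1 (0.0669) or Hsp72Tg MCAO 1 (0.112). WT sham 1 alone had a high cerebellar signal, with Gabra6 at 9.46 against 4.15 to 4.49 in the other 9 arrays. The other lists were not called with all arrays: oligodendrocyte markers (mean -0.14, Mog fell by 0.58, SE 0.12, with 2 higher and 3 lower adjusted over the list alone), oligodendrocyte precursor markers (-0.07, 1 higher adjusted over the list alone), cell cycle genes (0.06, Mcm3 rose by 0.61, SE 0.10; called higher without WT sham 2, adjusted p = 0.0417), choroid plexus markers (-0.07, 1 lower adjusted over the list alone), ependymal markers (-0.17, 2 lower adjusted over the list alone; called lower without Hsp72Tg MCAO 3, 0.0294), red blood cell genes (0.23, 4 genes measured; called higher without Hsp72Tg sham 1, 0.0418), hypothalamic and pituitary genes (-0.19) and thalamic markers (camera adjusted p = 0.642). Over all 32 lists camera called 20, 17 higher and 3 lower, against 0 with an estimated correlation and 13 by fry, and exact permutation of list means gave 16 lists with p under 0.05 and 0 after adjustment, where 100 arrangements allow a smallest p of 0.01.

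The study's own comparison takes the sham mice of each genotype as controls. In WT (3 MCAO arrays against 2 sham arrays), Ccl12 rose by 3.79 (SE 0.47), Cd44 by 3.42 (SE 0.46), Osmr by 3.23 (SE 0.31), the protease inhibitor Serpina3n by 2.94 (SE 0.38), Hspb1 by 2.93 (SE 0.36) and Lrg1, a secreted leucine-rich glycoprotein, by 2.73 (SE 0.36). S1pr3, a receptor for sphingosine 1-phosphate, rose by 1.85 (SE 0.21) and Pdlim4, a PDZ and LIM domain protein, by 1.5 (SE 0.12, adjusted p = 0.00561). The other genes that passed, named after their values were seen, were Hk2 (1.31) and the clone-named 1700047M11Rik (-0.99). With the mean over a gene's probe sets, Cd44, S1pr3, Lrg1 and Serpina3n no longer passed. Hspa1b at 3.04 (SE 0.46, adjusted p = 0.0865) and Hspa1a at 2.66 (SE 0.58, adjusted p = 0.155) did not pass. In all 10 genes passed in limma, 9 higher and 1 lower, and 1861 had an unadjusted p under 0.05 against 910 by chance. In 39% of genes the MCAO and sham arrays did not overlap, against 20% by chance. The count was 0 without WT sham 1, WT MCAO 1 or WT MCAO 3, 3 without WT MCAO 2 (Osmr, Pdlim4 and Fgfbp3), 8 without WT sham 2 with 2 of the 10 genes kept, 1 without Hsp72Tg sham 1 or Hsp72Tg sham 2 (Pdlim4), 463 without Hsp72Tg MCAO 1, 30 without Hsp72Tg MCAO 2 and 121 without Hsp72Tg MCAO 3. It was 955 when only the 5 WT arrays were fitted, and all 10 genes kept their sign in each fit without 1 array. Those 10 genes were chosen in the same arrays, so their kept sign is no independent support.

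The lists given here had the same sign of their mean in WT as over both genotypes. Of 13 pan-reactive astrocyte genes 5 rose over all genes (Cd44, Osmr, Serpina3n, Hspb1 and S1pr3) and 12 adjusted over the list alone (mean 2.42, interval 1.35 to 3.49), with adjusted p = 0.167 with an estimated correlation. This list alone was also called by fry (adjusted p = 0.0311). Of 12 A2 reactive astrocyte genes 0 passed in limma over all genes and 9 adjusted over the list alone (mean 1.89), and of 9 A1 genes 0 and 3 did (mean 0.77). Of 21 cytokines and chemokines 1 (Ccl12) and 9 rose (mean 1.37), and of 17 activated microglia and macrophage genes 0 and 13 (mean 0.91). Camera called these 4 lists higher, with adjusted p from 0.167 to 0.17 with an estimated correlation. Striatal projection neuron markers were called lower (mean -0.93, 0 over all genes in limma and 9 adjusted over the list alone), with adjusted p = 0.17 with an estimated correlation. Camera called 22 lists, 19 higher and 3 lower, against 0 with an estimated correlation. Calls that rested on single arrays were those of cerebellar markers without WT sham 1 (mean -1.11 with it and -0.0404 without it, adjusted p = 0.923), of hypoxia genes (mean 0.18, median -0.01, mean 0.116 without WT sham 1), which were lost without any of 7 arrays (WT sham 1, Hsp72Tg sham 1, Hsp72Tg sham 2, WT MCAO 2, WT MCAO 3, Hsp72Tg MCAO 2 and Hsp72Tg MCAO 3; adjusted p from 0.0505 to 0.204), of monocyte markers without WT MCAO 2 (0.0702), of neutrophil markers without WT MCAO 2 (0.0828) or WT sham 2 (0.488), and of neuronal markers without WT MCAO 3 (0.0566) or WT sham 2 (0.0563).

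In Hsp72Tg (3 MCAO arrays against 2 sham arrays), Hspa1b rose by 3.90 (SE 0.46, adjusted p = 0.0396), Osmr by 2.88 (SE 0.31, adjusted p = 0.0259) and Pdlim4 by 1.26 (SE 0.12, adjusted p = 0.0259), while Tph2 fell by 2.17 (SE 0.24, adjusted p = 0.0259). With the mean over its probe sets Osmr rose by 1.56 and still passed. The values of Tph2 in Hsp72Tg MCAO, 3.93 to 4.03, lie below the lower quartile of every array (at least 5.14), so the size of its fall is uncertain. With only probe sets above the median probe set, which leaves Tph2 out, the genes that passed were Hspa1b, Osmr, Pdlim4 and Hspb1. Hspa1a stood at 3.58 (SE 0.58, adjusted p = 0.183). Hspa1b, Osmr, Pdlim4 and Tph2 were all that passed in limma, 3 higher and 1 lower, and 2187 had an unadjusted p under 0.05 against 910 by chance. In 21.9% of genes the arrays of both groups did not overlap, against 20% by chance. Osmr and Pdlim4 passed in both genotypes. The count was 1181 without Hsp72Tg MCAO 1, with all 4 genes kept, 1 without WT MCAO 1 (Tph2), 1 without Hsp72Tg MCAO 3 (Pdlim4), and 0 without any of the other 7 arrays (WT sham 1, WT sham 2, Hsp72Tg sham 1, Hsp72Tg sham 2, WT MCAO 2, WT MCAO 3 and Hsp72Tg MCAO 2). It was 0 when only the 5 Hsp72Tg arrays were fitted.

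Of 13 pan-reactive astrocyte genes in Hsp72Tg 1 rose over all genes (Osmr) and 12 adjusted over the list alone (mean 2.12, interval 1.05 to 3.19). For 12 A2 genes the counts were 0 in limma and 9 (mean 1.44), for 9 A1 genes 0 and 1 (mean 0.75), for 21 cytokines and chemokines 0 and 12 (mean 1.44) and for 17 activated microglia and macrophage genes 0 and 5 (mean 0.67). Camera called these lists higher, with adjusted p = 0.21 for each with an estimated correlation. Striatal projection neuron markers were called lower (mean -0.57, 0 over all genes in limma or adjusted over the list alone), with adjusted p = 0.479 with an estimated correlation, and this call was lost without Hsp72Tg MCAO 3 (mean -0.29, adjusted p = 0.0528; mean -0.92 without Hsp72Tg MCAO 1) or Hsp72Tg sham 2 (0.0715). Camera called 17 lists, 15 higher and 2 lower, against 0 with an estimated correlation and 0 by fry. Other calls that rested on single arrays were those of complement genes without Hsp72Tg sham 2 (0.0534), of endothelial and blood-brain barrier markers without Hsp72Tg MCAO 3 (0.0765) or Hsp72Tg sham 1 (0.129), of heat shock proteins without Hsp72Tg MCAO 2 (0.0945), and of microglia markers of normal brain without Hsp72Tg MCAO 2 (0.473), Hsp72Tg sham 1 (0.126), Hsp72Tg sham 2 (0.123) or WT MCAO 1 (0.0539).

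The sizes of the MCAO change in both genotypes were set side by side over 18193 genes. Hspa1b changed more in Hsp72Tg (3.90 against 3.04) and Lcn2 less (3.73 against 5.04), where neither difference passed its test. Without Hsp72Tg MCAO 1 the Lcn2 change in Hsp72Tg was 5.31, above that in WT, so its direction rests on that array. Across genes Pearson's r was 0.755, with genes not independent replicates. The slope of the Hsp72Tg change on the WT change was 0.733 and that of the WT change on the Hsp72Tg change 0.777, and noise alone lowers both, so neither shows a smaller response. Among 263 genes with more than a 2-fold change in WT, 96.6% had the same sign in Hsp72Tg, with a median ratio of Hsp72Tg to WT of 0.774, which choosing genes by their WT change lowers. Among 204 genes chosen in Hsp72Tg instead, a choice made after seeing the data, the median ratio of WT to Hsp72Tg was 1.01. Without Hsp72Tg MCAO 1 the ratios were 1.05 and 0.702 (413 genes chosen in Hsp72Tg) and the slopes 0.996 and 0.603, so the order of the genotypes depends on that array. The correlation was 0.663 without WT sham 2, 0.644 without Hsp72Tg sham 2 and 0.639 without Hsp72Tg MCAO 3.

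**Figure D3:**
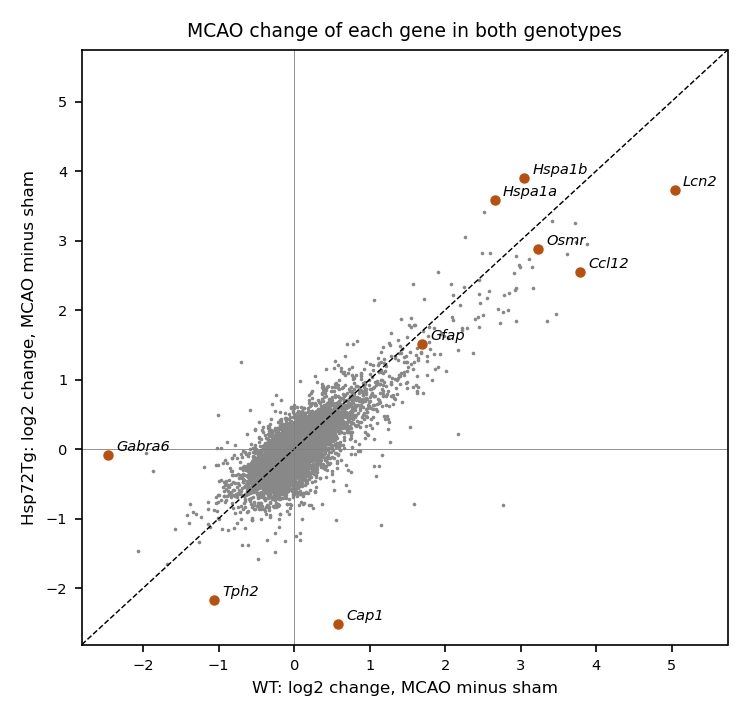
Log2 change after MCAO of each of 18193 genes in WT (horizontal) and Hsp72Tg (vertical). Each point is a gene, and the dashed line marks equal change.

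Whether the transgene changed the response to MCAO was tested as the difference of both MCAO changes. The genes with the smallest p, none of which passed, were higher for Oplah (0.58, SE 0.14), an enzyme of glutathione turnover, Ap1g2 (0.52, SE 0.14) and Fgfbp3 (0.71, SE 0.19), and lower for the cation channel Trpc4 (-0.68, SE 0.15), Mamdc2 (-0.77, SE 0.17) and Tmem267 (-1.30, SE 0.29). The difference was 0.85 for Hspa1b (SE 0.65, interval -0.60 to 2.31) and 0.93 for Hspa1a (SE 0.83, interval -0.92 to 2.78). Without Hsp72Tg MCAO 2 these were 0.39 and 0.30, without Hsp72Tg MCAO 1 they were 1.34 and 1.61, and that of Hspa1b was 0.54 without WT MCAO 1. In limma 0 genes passed and 319 had an unadjusted p under 0.05, fewer than the 910 that chance gives. The count was 2 without WT sham 2 (Gabra6 and Pcp2) and 2 without Hsp72Tg MCAO 1 (Cap1, -4.52, and Tmem87a, -1.96), genes named after their values were seen.

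For the same difference camera called 9 lists, 5 higher and 4 lower, against 0 with an estimated correlation, 0 by fry and 0 by exact permutation, where the smallest possible p is 0.0167 and 0 lists had p under 0.05 before adjustment. Every call was lost without Hsp72Tg sham 2 (adjusted p from 0.0544 to 0.504). Immediate early genes had a smaller change in Hsp72Tg (mean -0.65, interval -1.99 to 0.69; -0.39 without Hsp72Tg MCAO 1 and -1.05 without Hsp72Tg MCAO 2), with Fos at -1.94 (SE 1.0), Egr2 at -2.25 (SE 0.87) and Arc at -1.57 (SE 0.77). Thalamic markers had a mean of -0.39 (interval -0.74 to -0.04), with Shox2 at -0.76 (SE 0.32), Ntng1 at -0.71 (SE 0.21) and the kinase Prkcd at -0.65 (SE 0.23). For both lists adjusted p = 0.898 with an estimated correlation. Striatal projection neuron markers had a mean of 0.36, with Ppp1r1b, the phosphatase regulator of dopamine-responsive neurons, at 0.81 (SE 0.40), and the call was also lost without Hsp72Tg MCAO 1 (mean 0.00874, adjusted p = 0.762) or Hsp72Tg sham 1 (0.144), while the mean was 0.64 without Hsp72Tg MCAO 3. Activated microglia and macrophage genes had a mean of -0.24 (-0.36 without Hsp72Tg sham 2 and -0.44 without Hsp72Tg MCAO 3) and were also lost without Hsp72Tg MCAO 1 (mean -0.0725, 0.821), Hsp72Tg sham 1 (mean -0.11, 0.263), WT MCAO 2 (0.156) or WT sham 1 (mean -0.14, 0.327). Cerebellar markers had a mean of 0.98 (2.05 without WT sham 2), which turned without WT sham 1 (mean -0.0908, 0.349) and was lost without Hsp72Tg sham 1 (0.174). For these 3 lists too adjusted p = 0.898 with an estimated correlation. Pan-reactive astrocyte genes, the list closest to the series' question, were not called for this difference, with an exact permutation p = 0.717, but camera called them lower without Hsp72Tg MCAO 2 (adjusted p = 0.0181) or Hsp72Tg MCAO 3 (2e-04). This direction rests on Hsp72Tg MCAO 1, where the list mean relative to WT sham was 1.29. It was 2.58 and 2.80 in the other Hsp72Tg MCAO arrays and 2.295 to 2.574 in WT MCAO. The A2 list (mean -0.45, camera adjusted p = 0.0654) was not called with all arrays either. Camera called it lower without WT MCAO 1 (0.0352), Hsp72Tg MCAO 2 (0.000279) or Hsp72Tg MCAO 3 (9.46e-05), and the A1 list (mean -0.02) higher without Hsp72Tg MCAO 1 (0.0102). The lower A2 value also rests on Hsp72Tg MCAO 1, where its mean relative to WT sham was 0.61. The A2 mean was 2.02 and 2.13 in the other Hsp72Tg MCAO arrays and 1.77 to 2.03 in WT MCAO.

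After MCAO, Hsp72Tg was compared with WT directly, with 3 arrays against 3. The genes with the smallest p, none of which passed, were higher for Cd6 (0.38, SE 0.08), Dap3 (0.48, SE 0.11) and the glial connexin Gjc3 (0.47, SE 0.11), and lower for Trpc4 (-0.64, SE 0.09), Mamdc2 (-0.69, SE 0.11) and Shisa6 (-1.12, SE 0.19). In limma 0 genes passed and 487 had an unadjusted p under 0.05 against 910 by chance. Without Hsp72Tg MCAO 3 the count was 5, all lower in Hsp72Tg and named after their values were seen: the transglutaminase Tgm1 (-2.20), Ms4a6d (-1.80), Ms4a6c (-1.24), Capg (-1.02) and Plce1 (-0.91). Camera called 6 lists, 5 higher and 1 lower, against 0 with an estimated correlation and 0 by fry, and 20 arrangements of 3 against 3 allow no exact p under 0.1.

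Among those lists after MCAO, thalamic markers were lower in Hsp72Tg (mean -0.36, interval -0.58 to -0.14), with 0 over all genes in limma and 6 of 9 lower adjusted over the list alone, among them Prkcd (-0.64, SE 0.14), Shox2 (-0.65, SE 0.20) and Zic1 (-0.63, SE 0.23), and adjusted p = 0.799 with an estimated correlation. Striatal projection neuron markers were higher in value in 10 of 10 (mean 0.46, interval -0.30 to 1.21), with adjusted p = 0.889 with an estimated correlation, and without Hsp72Tg MCAO 1 the mean was 0.10 and the call was lost (adjusted p = 0.0868), while without Hsp72Tg MCAO 3 the mean was 0.74. Immediate early genes (mean 0.20, 0.47 without Hsp72Tg MCAO 1 and 0.33 without Hsp72Tg MCAO 3) were called higher with all arrays and lower without Hsp72Tg MCAO 2 (mean -0.19, adjusted p = 0.0124), and the call was lost without WT MCAO 2 (0.199), WT MCAO 3 (0.129), Hsp72Tg sham 1 or Hsp72Tg sham 2 (0.06 each). Astrocyte markers of normal brain (mean 0.05, 0.11 without Hsp72Tg MCAO 1) turned without Hsp72Tg MCAO 2 (mean -0.0269, 0.989) and were lost without WT MCAO 1 (0.051) or WT MCAO 3 (0.118). For the 2 last lists adjusted p = 0.935 with an estimated correlation. Oligodendrocyte markers (mean 0.10, 0.19 without Hsp72Tg MCAO 1) were lost without Hsp72Tg MCAO 2 (0.0561), Hsp72Tg MCAO 3 (mean 0.0258, 0.271) or WT MCAO 1 (mean 0.0651, 0.0967), and choroid plexus markers (mean 0.15, 0.23 without WT MCAO 3) without Hsp72Tg MCAO 3 (mean 0.0602, 0.436), WT MCAO 1 (0.0642) or WT MCAO 2 (0.0889), both with adjusted p = 0.889 with an estimated correlation. Pan-reactive astrocyte genes were not called with all arrays (adjusted p = 0.195), and the direction depended on the array left out: higher without Hsp72Tg MCAO 1 (0.00529), lower without Hsp72Tg MCAO 2 (0.0124) or Hsp72Tg MCAO 3 (9.73e-05). The number of lists called was 18 without Hsp72Tg MCAO 1, 13 without Hsp72Tg MCAO 2 and 12 without Hsp72Tg MCAO 3.

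After sham surgery, with 2 arrays against 2, the genes with the smallest p, none of which passed, were higher in Hsp72Tg for Tmem267 (1.38, SE 0.23), Zscan29 (0.84, SE 0.16) and the lipase Lpl (0.72, SE 0.16), and lower for the glyoxalase Glo1 (-0.80, SE 0.18), Ccdc30 (-0.60, SE 0.14) and the kinase Mapk12 (-0.49, SE 0.12). Ccdc30 has 7 probe sets, and its direction depends on the one used. Another of them was higher in Hsp72Tg sham (6.499 and 6.581) than in WT sham (6.075 and 6.139). In limma 0 genes passed and 283 had an unadjusted p under 0.05 against 910 by chance. The count was 3 without WT sham 2 (Gabra6, Pcp2 and Cbln3, genes of the cerebellum), 2 without Hsp72Tg MCAO 1 (Cap1, 4.28, and Tmem87a, 2.05) and 3 with only the 4 sham arrays (Cap1, Tmem87a and Rbm45, 2.38), all named after their values were seen. Camera called 3 lists against 0 with an estimated correlation and 0 by fry. Immediate early genes were higher in Hsp72Tg sham (mean 0.85, interval -0.18 to 1.89, 22 of 23 higher in value), with 0 over all genes in limma and 5 higher adjusted over the list alone, among them Egr2 (2.60, SE 0.67) and Fos (2.11, SE 0.77), and adjusted p = 0.419 with an estimated correlation. Heat shock proteins and co-chaperones were called higher (mean 0.17, adjusted p = 0.682 with an estimated correlation), a call that was lost without Hsp72Tg sham 2 (adjusted p = 0.244). Cerebellar markers were called lower (mean -1.04, adjusted p = 0.419 with an estimated correlation) and turned without WT sham 1 (mean 0.0235, adjusted p = 0.591), while the mean was -2.11 without WT sham 2. The number of lists called was 8 without WT sham 2 and 5 without Hsp72Tg MCAO 1.

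Over both surgeries, with 5 arrays against 5, the genes with the smallest p were higher in Hsp72Tg for Cdr1os (0.53, SE 0.10), Zscan29 (0.53, SE 0.10) and Tmem267 (0.72, SE 0.15), and lower for Ccdc30 (-0.43, SE 0.09), Shisa6 (-0.70, SE 0.15) and the desmosomal protein Pkp2 (-0.51, SE 0.11). The value of Ccdc30 is from the same probe set as after sham surgery, where another went the other way. None passed. Tmem267 hardly differed after MCAO, with means of 8.98 in Hsp72Tg and 8.91 in WT, against 9.23 and 7.85 after sham surgery. Zscan29 read 5.34 and 5.32 in Hsp72Tg MCAO 2 and Hsp72Tg MCAO 3, within the WT arrays (5.06 to 5.37), and 5.72 in Hsp72Tg MCAO 1. Cdr1os was higher in Hsp72Tg after MCAO too, with means of 5.21 against 4.83 in WT. All WT MCAO arrays (4.64 to 4.98) and Hsp72Tg MCAO 2 (5.00) lay below the lower quartile of every array (at least 5.14). The size of this difference is thus uncertain. In limma 0 genes passed and 390 had an unadjusted p under 0.05 against 910 by chance. The count was 2 without WT sham 2 (Gabra6, -2.56, and Pcp2, -2.11) and 2 without Hsp72Tg MCAO 1 (Cap1, 2.02, and Tmem87a, 1.07), named after their values were seen.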

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

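Of the tests in this part, the counts of other splits of the arrays were planned, except that for lists over both genotypes, and the other tests were chosen after the result was seen, including their statistics and limits. For the regional tests only the gene lists were fixed before their values were looked at. The statistic against a wrong surgery label was changed once and a second version of the dilution test was added after values were seen. The test of neighbouring genes was changed once after its first outcome, and both outcomes are given.

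The difference of the MCAO changes between genotypes passed camera at its preset correlation for 9 lists. The mean differences were -0.12 for heat shock proteins and co-chaperones, 0.0943 for astrocyte markers of normal brain, 0.36 for striatal projection neuron markers, -0.24 for activated microglia and macrophage genes, 0.14 for lymphocyte markers, -0.65 for immediate early genes, 0.18 for choroid plexus markers, -0.39 for thalamic markers and 0.98 for cerebellar markers. For all 9 lists adjusted p = 0.898 with an estimated correlation. The 4 lists not described in the report's account of this difference were each lost without several arrays, with means from -0.29 (without Hsp72Tg MCAO 2) to 0.0321 (without Hsp72Tg MCAO 1) for heat shock proteins, 0.0153 (without Hsp72Tg MCAO 2), 0.059 (without Hsp72Tg sham 1), 0.0605 (without WT sham 1) and 0.147 (without Hsp72Tg MCAO 1) for astrocyte markers, and 0.087 (without Hsp72Tg MCAO 3) for choroid plexus markers. The calls were lost for heat shock proteins without Hsp72Tg MCAO 1, Hsp72Tg MCAO 3, Hsp72Tg sham 2, WT MCAO 2, WT MCAO 3 or WT sham 1 (adjusted p from 0.107 to 0.909), astrocyte markers of normal brain without Hsp72Tg MCAO 2, Hsp72Tg sham 1, Hsp72Tg sham 2 or WT sham 1 (0.0544 to 0.535), lymphocyte markers without Hsp72Tg MCAO 1, Hsp72Tg MCAO 3, Hsp72Tg sham 2 or WT sham 1 (0.0637 to 0.265) and choroid plexus markers without any of 7 arrays (Hsp72Tg MCAO 3, Hsp72Tg sham 1, Hsp72Tg sham 2, WT MCAO 1, WT MCAO 2, WT sham 1 and WT sham 2; 0.053 to 0.452). Immediate early genes were lost without Hsp72Tg sham 2 (0.104), and thalamic markers too (0.227). As many lists or more were called in 36 of the 60 splits of the arrays within surgery, and another split gave 20, so chance cannot be excluded.

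Other splits of the arrays were counted for the gene counts as well. For MCAO over both genotypes, 3 of 100 splits within genotype gave 266 genes or more, the real split included. That share is under 0.05 but was not adjusted over the other split tests, and the real split did not give the most genes. Chance is thus not excluded. The others of these 3 splits reached up to 958 genes. They grouped the sham arrays with Hsp72Tg MCAO 1 and a WT MCAO array, which points to a structure of the samples. For the lists of that comparison 17 of 100 splits called 20 lists or more, with up to 22, so chance cannot be excluded. With 0 genes for the difference of the MCAO changes and 0 for genotype over both surgeries, all 60 of 60 splits gave as many, and the highest other count was 1 for each. The 10 splits of the 6 MCAO arrays are too few for a share under 0.05. There the real count was 0 and the highest other 0, as all 10 splits gave.

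The 18S ribosomal RNA control probe set, outside the main measurement, read 10.52 in WT MCAO 1 and 10.79 in Hsp72Tg MCAO 2, above the highest sham array at 8.48 and the highest other MCAO array at 8.56. Without these 2 arrays, a setting chosen after seeing the data, 18 genes passed for MCAO over both genotypes. Without WT MCAO 1 alone 27 passed and without Hsp72Tg MCAO 2 alone 222. A low count is not particular to arrays with high 18S readings, as 15 genes passed without WT MCAO 3 alone, which read 8.03.

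Hsp72Tg MCAO 1 lay near the sham arrays. A sham array under an MCAO label is argued against by its Hspa1b value of 12.06, against 9.12 to 9.48 in the sham arrays. Among 1096 genes that the other 9 arrays call higher, this array exceeded 3 sham arrays in 50.8%. The share was at most 33.1% for a sham array and at least 94.9% for the other MCAO arrays. Those arrays helped choose the genes, so a sham array left out of the choice could exceed 33.1%, and these shares decide nothing. Even dilution of injured with uninjured tissue stays open: of the change in signal intensity (not log2), the median share reached by pan-reactive astrocyte genes was 1.95 times that for all genes that rose and 2.01 times that for 959 genes of at least their lowest level and change, against at most 1.28 in the other MCAO arrays. The 959 genes were not matched further on change, the shares of the 13 genes ran from -0.283 for Steap4 to 1.09 for Gfap, and their median of 0.29 lay within the quartiles of all genes that rose (-0.00398 to 0.328), so these ratios exclude nothing. A smaller or differently placed injury in this sample may account for the pattern and stays open. Its striatal marker mean, relative to WT sham, was 0.23, above every sham array (at most 0.15). In the other MCAO arrays it lay between -1.06 and -0.62.

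Regional markers differed between arrays of a group, where no biological explanation was tested. A second list of 8 measured cerebellar genes was 0.84 higher in WT sham 1 than in any other array (SD of the others 0.08), which is consistent with cerebellar tissue in that sample. A list of 6 olfactory bulb genes was 0.60 higher in WT sham 2, Hsp72Tg sham 1 and WT MCAO 2 than in all others (SD 0.08), which is consistent with olfactory bulb tissue in those 3. Less ventral midbrain tissue in WT MCAO 2 and Hsp72Tg MCAO 1, where the dopamine transporter Slc6a3 read 6.47 and 5.89 against at least 7.82 elsewhere, stays open. The mean of 7 further midbrain genes was lower in both (6.08 and 6.22) than in each of the other 8 arrays (at least 6.28), as less such tissue would give, but the smallest gap of 0.0639 (SD of the others 0.0456) was under the limit of 2 SD, which was set after the values were seen.

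Cap1 (10.14 to 10.57) and Tmem87a (8.51 to 8.72) were high in both Hsp72Tg sham arrays and Hsp72Tg MCAO 1, and low in the other 7 arrays (at most 6.59 and 6.83), Hsp72Tg MCAO 2 and Hsp72Tg MCAO 3 included. A strain variant present in these 3 samples may place such genes near each other in the genome (gene order of GRCm38.p6). The first test, with 1 probe set per gene and a gap over 0.5, found these 2 genes and 0 pairs of neighbours (permutation p = 1), and the second, set after that outcome and after gene positions had been seen, with every probe set and a gap over 0.25, found 19 pairs among 18 genes (permutation p = 1e-05, the smallest 100000 random sets can give, with up to 13 pairs). These were 12.4% of the possible pairs, against 1.09% to 2.33% for 8 of the other sets of 3 arrays among the 10 with most pairs and 21.4% (6 pairs among 8 genes) for WT sham 1, WT sham 2 and WT MCAO 1, and the explanation stays open because the first test had too few genes and the second was set after positions were seen. A wrong genotype label on Hsp72Tg MCAO 2 and Hsp72Tg MCAO 3 stays open too: these 2 arrays had the highest values in all 4 Hspa1a and Hspa1b probe sets (Hspa1b 13.96 and 13.09, WT MCAO at most 12.84), as their labels say, but MCAO raises both genes, Hsp72Tg MCAO 1 lay within the WT MCAO range, and Hspa1b did not separate the genotypes after sham surgery (lowest Hsp72Tg array minus highest WT array -0.36).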

How the results depend on the processing

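The fits without 2 arrays, the list tests for MCAO over both genotypes and the exact list tests were chosen after seeing the data; the other alternatives were planned. The labels do not say that each array is a separate animal, so p-values measure the spread between these samples. The counts of genes depend on single arrays and on how the spread is modelled, and a fit that leaves a group with 1 array assumes that it varies like the others. In the comparisons of genotypes 283 to 487 genes had an unadjusted p under 0.05 in limma, against 910 by chance. Their p-values thus ran high, so 0 genes passing is weak evidence that the genotypes are alike. Signal over background was not used here, so dim probe sets stayed in. The alternative for values not on a log scale was not run, as it does not apply, and fitting only the arrays of the groups compared is the same fit for the 3 comparisons that use all arrays. Except where the construction shows the cause (fewer arrays, fewer genes or a stricter threshold), the cause was not tested.

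Whether the replicate numbers pair the samples stays open. Of 13 pairs of same-numbered arrays 2 correlated over 0.1 (r from -0.16 to 0.25), but differently numbered pairs were not measured as a baseline. With the replicate number as a block the gene counts were 0 for MCAO in WT, 0 for MCAO in Hsp72Tg and 19 for MCAO over both genotypes, 5 lists were called for genotype after sham surgery, and 35 of 311 changes of named genes no longer passed.

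For MCAO in WT (10 genes) the count was 1358 with limma's arrayWeights, 955 with only the WT arrays, 6 with the mean over probe sets, 2 with every probe set, 1 at an adjusted p under 0.01, and 0 to 463 leaving out each array. For MCAO in Hsp72Tg (4 genes) it was 0 with every probe set, 0 with only the Hsp72Tg arrays, 0 at an adjusted p under 0.01, and 0 to 1181 leaving out each array. For MCAO over both genotypes (266 genes) it was 1116 with arrayWeights, 15 at an adjusted p under 0.01, 106 with at least a 2-fold change, and 11 to 2251 leaving out each array. Leaving out each array gave 0 to 2 genes for the difference of the MCAO changes, 0 to 5 for genotype after MCAO, 0 to 3 after sham surgery and 0 to 2 over both surgeries, and only the sham arrays gave 3 after sham surgery. Without WT sham 1 and Hsp72Tg MCAO 1 the counts were 148 for MCAO in WT, 780 in Hsp72Tg, 1177 over both genotypes, 1 for the difference, 2 for genotype after sham surgery and 1 over both surgeries. Without WT MCAO 1 and Hsp72Tg MCAO 2 they were 4, 2 and 18 for MCAO in WT, in Hsp72Tg and over both.

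Lists called fell to 0 for every comparison with an estimated correlation. By fry they were 1 for MCAO in WT, 13 over both genotypes and 0 for MCAO in Hsp72Tg and the 3 comparisons of genotypes, and by exact permutation 0 for MCAO over both genotypes and 0 for the difference of the MCAO changes. The filter on dim probe sets gave 7 lists for genotype after sham surgery. Leaving out each array gave 0 to 14 lists for the difference, 4 to 18 for genotype after MCAO and 2 to 8 after sham surgery. Without WT sham 1 and Hsp72Tg MCAO 1 these were 17 after MCAO and 5 after sham surgery, and without WT MCAO 1 and Hsp72Tg MCAO 2 they were 13 after MCAO. The correlation of the MCAO changes ran from 0.639 to 0.776 leaving out each array.

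Of 3110 changes of named genes without 1 array, 2689 stayed on their side of the threshold with their sign, 245 no longer passed, 160 newly passed and 16 reversed. Without WT sham 1 Gabra6 and Pcp2 reversed to 0.190 and 0.162 for MCAO in WT (lowest without another array -5.12 and -4.08), -0.276 and -0.223 for the difference (highest 5.03 and 4.02), 0.236 and 0.119 after sham surgery (lowest -5.07 and -4.12) and 0.0524 and 0.0507 for MCAO over both genotypes (lowest -2.60 and -2.07). For the difference, Drd2 reversed to -0.0584 (highest 0.660) and Lgals3 to 0.418 (lowest -1.04) without Hsp72Tg MCAO 1 and Aqp1 to -0.0888 (highest 0.552) without Hsp72Tg sham 2. After MCAO, Opalin reversed to -0.0660 (highest 0.860) and Npas4 to -0.331 (highest 1.76) without Hsp72Tg MCAO 2. Hspa1a after sham surgery reversed to 0.0359 (lowest -0.212) without Hsp72Tg sham 1, and Hspa1b over both surgeries to -0.0197 without WT MCAO 1 and -0.0950 without Hsp72Tg MCAO 2 (highest 0.381). Of the 311 changes of named genes, 10 no longer passed with quantile normalization, 2 with median centring and 10 with the mean over probe sets. For MCAO over both genotypes, probe sets of Hspa4 and of H2-D1 changed in opposite directions. This check did not cover the comparisons of genotypes.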

Other observations

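The genes in this part were singled out, and its test chosen, after their values were seen. Among genes that fell over both genotypes were the serotonergic genes Tph2 (-1.62, SE 0.17) and Slc6a4, the serotonin transporter (-1.03, SE 0.13), the striatal receptor Gpr6 (-1.77, SE 0.35), the signalling gene Rasgrp2 (-1.37, SE 0.21), the tryptophan-degrading enzyme Ido1 (-1.12, SE 0.18) and the peptidase Mme (-1.0, SE 0.17). Tph2 lay between 5.39 and 6.42 in the sham arrays and between 3.93 and 4.86 in the MCAO arrays, below the lower quartile of every array (at least 5.14), so the size of its fall is uncertain. Less raphe tissue in the MCAO samples may lower such genes, and a list of 5 serotonergic genes (4 measured), written after Tph2 and Slc6a4 were seen and holding both, had a change of -0.865 (SE 0.0654). However, a second list of serotonergic genes (5 of 7 measured) had a change of 0.1 (SE 0.115), not lower, and part of its genes are expressed outside the raphe, so the explanation stays open.

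Some genes, among them the myeloid genes Arg1 and Chil3, were high in a part of the MCAO arrays. Arg1, the arginase of alternatively activated macrophages, read 8.42 in Hsp72Tg MCAO 3, 7.59 in WT MCAO 2 and 7.28 in WT MCAO 3, against 5.6 in WT MCAO 1, 4.85 in Hsp72Tg MCAO 2 and 4.61 in Hsp72Tg MCAO 1. Chil3 read 7.65, 7.15 and 6.41 in the first 3 of these arrays and 6.38 in Hsp72Tg MCAO 2, against 4.49 in WT MCAO 1 and 4.44 in Hsp72Tg MCAO 1. Ifi202b read 9.43 in WT MCAO 1, 8.60 in WT MCAO 3, 8.60 in Hsp72Tg MCAO 3 and 7.30 in Hsp72Tg MCAO 2, against 4.43 to 4.69 in the other 6 arrays. Rbm45 read 6.76 and 6.75 in the WT sham arrays and 9.19 and 9.07 in the Hsp72Tg sham arrays, and between 7.24 and 9.04 in the MCAO arrays, without a split by genotype. Of 46 genes that split the arrays with a gap over 1, 26 were high only in the 5 MCAO arrays other than Hsp72Tg MCAO 1, and 1, Gpr6, was low only in these.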
